A study of Homo sapiens with 2 samples.

How the data were processed

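RNA was sequenced from RKO cells, an established human colon carcinoma line, collected 48 h after transfection with a control siRNA or an siRNA against SRSF1. Each group held 1 library. Groups were taken from the sample labels. The deposited gene table gave 1 FPKM value (fragments per kilobase of gene model, scaled to the fragments of the library) per gene and library, calculated by the authors. Per the submitters' processing notes, the reads were processed with Bowtie 0.12.2 and genome build hg19. The aligner options, the counting tool, the gene annotation, the strand setting, the filters and whether poly(A) RNA was selected are not given in the sources used here, which name both mRNA profiles and total RNA. A deposited mapping summary per library listed the authors' read counts and, per the file headers, the fraction of mapped reads on each chromosome. Chromosome M was listed there at 16569 bases.

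The table held 40205 rows with no symbol listed more than once, so no rows had to be summed. Of these, 16235 were above 0 in both libraries, 2413 in 1 library only, and 21557 were at 0 in both. The measure of change was the difference in log2(FPKM + 1), SRSF1 siRNA minus control siRNA, which understates the change of genes with low values. Changes given as times or fold for a single gene are plain ratios of the FPKM values, without a pseudocount, whereas the 2-fold and 1.5-fold rules use the log2(FPKM + 1) difference. Genes with a mean FPKM of at least 1 over both libraries were kept, which left 11274. A single gene was said to have risen or fallen only where this difference reached 2-fold. Since each group had 1 library, no p-values were calculated.

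Whole fragment counts were recovered from the FPKM values, because FPKM equals the count times a constant divided by the length of the gene model and the library total. The totals that made the values whole were 23138519 fragments for control siRNA and 23852089 for SRSF1 siRNA. With these totals, all 16235 genes above 0 in both libraries gave whole counts and a whole length within a relative tolerance of 2e-12. With the control total raised by 1, the share was 0%. The recovered counts were the smallest that fit, and the true count of a gene could be a whole multiple. Counts were used for exact Clopper-Pearson 95% intervals of the ratio between the libraries, conditional on their sum, for 1 alternative, for a simulation of counting error and for sums over genes. Sums over histone genes were repeated, as a check chosen after seeing the data, with each row's counts at the whole multiple nearest its annotated transcript length, and with the multiples that gave the lowest ratio, up to the longest gene model of these rows, 4507 bases. These intervals cover counting error only, and copies made by PCR are not independent molecules. The median count per expressed gene was 618 in the control library and 596 in the SRSF1 siRNA library. Shares of mapped reads have Wilson 95% intervals.

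In total, 38 gene lists with 819 entries, the rule for named genes and the alternatives were fixed before the data were examined. A list with at least 5 measured members was compared with 10000 random lists of the same size, matched on mean expression in 20 bins. It was said to stand apart where its median lay below percentile 2.5 or above percentile 97.5 of the random medians. For each list, the members at least 1.5-fold higher and lower were counted. The named genes were SRSF1, and the 12 genes with the largest rise and the 12 with the largest fall among symbols with a mean FPKM of at least 5, leaving out unnamed loci and small RNA symbols. To these were added 4 members of each list that stood apart, chosen by size of change in the direction of the median, and up to 2 members of every other list. The other SR protein genes, DBF4B, DBF4 and CDC7, and the reference genes ACTB, GAPDH and TBP completed the rule.

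Transcript length and GC content were those of the longest transcript of each gene in GENCODE 29, matched by symbol, with older symbols found through RefSeq synonyms. A value was found for 10869 expressed genes (96.4%) and for every expressed member of each list. The trend was removed with additive lowess curves with a span of 0.3. Coordinates are those of GENCODE 29 on GRCh38. They differ from those of hg19 and were used only to locate genes and to look for overlapping exons.

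The steps were tested on simulated libraries drawn from the real means of the 11274 genes of this comparison, with 200 genes changed and an SD of 0.1 on the natural log scale between libraries. Both library totals were recovered exactly. The recovered counts equalled the true ones in 85.4% of genes, and in 100% the true count was a whole multiple. The share of changed genes past the 2-fold rule was 0% for true changes of 1.5-fold, 22% for 2-fold, 90% for 3-fold and 94% for 4-fold. Of 11074 unchanged genes, 39 passed the rule. Of the random lists of 20 genes, 6% were called with no shift and 100% when every member was shifted by 0.2. The simulated genes varied independently and all members shifted equally, so both list rates may be too favourable for real lists. In the data the log2 difference had an SD of 0.29 across genes, where counting error alone gave 0.16. The simulated libraries may thus vary less than the real ones, and the rates for single genes may be too favourable as well.

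Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, rescaling to a median ratio of 0 on the log2 scale, rescaling of each column to 1 fixed sum, quantile normalization, size rules of 1.5-fold and 3-fold, unmatched random lists and the mean of the list. Chosen after seeing the data were the ratio of whole counts without a pseudocount for genes with at least 20 fragments, protein-coding and mitochondrially encoded rows only, library totals without mitochondrial rows, and removal of the length and GC trend. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.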

Results

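Transcript levels were measured in RKO cells, a human colon carcinoma line, 48 h after transfection with a control siRNA or with an siRNA against SRSF1. SRSF1 encodes an SR protein, a regulator of pre-mRNA splicing. There was 1 library per group, so none of the differences below has a replicate check. The control library held 64651910 reads, of which 70.4% mapped, and the SRSF1 siRNA library held 61879680 reads, of which 75.9% mapped. Reads that crossed an exon junction made up 47.1% of mapped reads in the control library and 45.2% in the SRSF1 siRNA library. Chromosome M took 6.60% and 8.39% of mapped reads. Among reads on nuclear chromosomes, the share of each autosome in the SRSF1 siRNA library was between 0.971 times (chromosome 22) and 1.06 times (chromosome 10) its share in the control library.

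SRSF1 itself fell from 103 to 32.7 FPKM, which left 31.7% of the control level (95% counting interval 30.6% to 32.8%). Among protein-coding genes with a mean FPKM of at least 5 it had the lowest log2(FPKM + 1) difference, at -1.63. In GENCODE 29 on GRCh38 the gene lies on the minus strand of chromosome 17, from 58003360 to 58007346. The transcripts of the other SR protein genes stayed within 1.5-fold. SRSF6 was at 1.31 times its control level (1.27 to 1.35), whereas TRA2A was at 0.763 times (0.693 to 0.840), TRA2B at 0.809 times (0.773 to 0.848) and SRSF7 at 0.826 times (0.801 to 0.852). SRSF2, SRSF3, SRSF5 and SRSF8 were at 0.836, 0.876, 0.912 and 0.824 times. SRSF4, SRSF9, SRSF10 and SRSF11 were between 0.970 and 1.01 times, and SRSF12 was listed at 0 in both libraries.

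The comparison of the libraries asks which transcripts differ once SRSF1 is depleted. The sequence and number of the siRNAs are not in the sample labels, so direct silencing of other genes cannot be told apart from effects of SRSF1 loss. Few expressed genes differed by 2-fold: 32 rose and 49 fell, out of 11274. Rows of type mRNA made up 10064 of the 11274, but only 10 of those that rose and 13 of those that fell. The other 22 and 36 were rows of other types, among them 5 and 11 of 178 snoRNA rows. The core histone gene HIST1H2BK rose most among named genes on the log2(FPKM + 1) scale, from 32.2 to 138 FPKM (4.29-fold, counting interval 3.93 to 4.69), and HIST1H2BD rose from 5.53 to 15.6 FPKM. ATP6V1D, a subunit of the proton pump of lysosomes, rose from 26.9 to 60.1 FPKM (2.23-fold, 2.02 to 2.47). Among the genes that fell were CCND1, which encodes the G1 cyclin D1, from 60.9 to 26.1 FPKM (0.429-fold, 0.410 to 0.449), and MYEOV, from 12.4 to 3.37 FPKM (0.272-fold, 0.215 to 0.342).

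**Figure D1:**
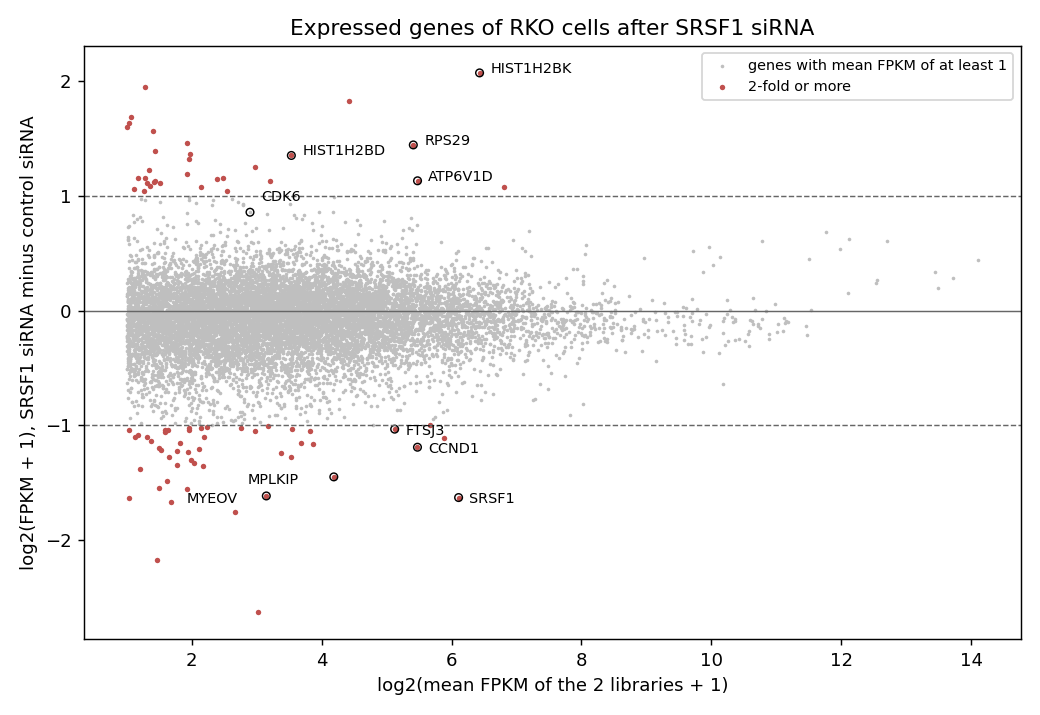
Each point is 1 of the 11274 genes with a mean FPKM of at least 1, with log2(mean FPKM + 1) on the x axis and the log2(FPKM + 1) difference, SRSF1 siRNA minus control siRNA, on the y axis. The 32 genes above the upper dashed line and the 49 below the lower one differ by 2-fold or more, and SRSF1 lies at -1.63.

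Other genes with the largest falls act in several processes. MPLKIP, mutated in a form of trichothiodystrophy, fell from 25.7 to 8.78 FPKM (0.342-fold, 0.289 to 0.403). ELP2, a subunit of the Elongator complex that modifies tRNA, fell from 19.1 to 7.97 FPKM. FTSJ3, a methyltransferase of ribosome assembly, fell from 45.9 to 21.9 FPKM (0.478-fold, 0.452 to 0.505), and TRMT1L, related to a tRNA methyltransferase, fell from 14.7 to 6.71 FPKM. MAP1LC3C, a paralog in the LC3 family of autophagy proteins, fell from 79.9 to 36.6 FPKM. C9orf123, OXLD1 and WDR54 fell to 0.453, 0.429 and 0.454 times their control levels. RFC1, the large subunit of the clamp loader of DNA replication, was at 0.488 times (0.463 to 0.515), with a log2(FPKM + 1) difference of -0.99 just short of the 2-fold rule.

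On the higher side, VAMP2, a SNARE protein of vesicle fusion, was at 2.18 times its control level (1.84 to 2.59), and CAB39L, an activator partner of the kinase LKB1, at 2.13 times (1.86 to 2.44). CDK6, a kinase partner of D-type cyclins, went from 4.30 to 8.60 FPKM (counting interval of the fold 1.86 to 2.14), and PDP1, a phosphatase that activates pyruvate dehydrogenase, was at 1.88 times (1.71 to 2.07). None of these 4 passed the 2-fold rule on the log2(FPKM + 1) scale. RPS29 rose from 21.9 to 61.2 FPKM and the pseudogene RPL32P29 from 8.41 to 32.3 FPKM, but their exons overlap on the same strand in GENCODE 29, so both values are uncertain. The mitochondrial tRNA gene TRNL2 rose on only 6 and 17 fragments (2.75-fold, 1.03 to 8.51). Exons of another annotated gene overlapped 11 of the 22 genes with the largest rises and falls that could be looked up, and the strand setting of the counting is not known. The overlapping gene lies on the opposite strand for CCND1, ATP6V1D, OXLD1 and FTSJ3. For SRSF1 and VAMP2 a protein-coding gene on the same strand overlaps, so their values could hold its reads or lack shared ones.

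Counting error limits the 2-fold counts: with no difference simulated, it alone, from the smallest counts that fit and so overstated for some genes, put a median of 23 genes above and 22 below the 2-fold limits, and the counting interval excluded 1 for 16 of the genes that rose and for 31 of those that fell. Under quantile normalization, 45 genes were higher and 33 lower, against 32 and 49 in the FPKM as deposited. With a mean FPKM of at least 5 there were 8 and 18, where simulated counting error alone gave at most 9 and 7. With a pseudocount of 0.1 there were 67 and 165, with columns rescaled to a fixed sum 85 and 141, and from whole counts without a pseudocount 33 and 154. The median log2(FPKM + 1) difference over the expressed genes was -0.06, with an SD of 0.29 across genes.

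Histone genes formed the list with the highest median, 0.66 over the 22 members with a mean FPKM of at least 1, above all random lists. With no filter on low values it was 0.20 over 39 members, again above all. At least 1.5-fold higher were 12 members and lower were 2. Beside HIST1H2BK and HIST1H2BD, HIST1H2BJ rose from 1.02 to 4.56 FPKM (4.45-fold, 2.79 to 7.42) and HIST1H4H from 1.23 to 4.56 FPKM (3.70-fold, 2.49 to 5.64), while HIST1H2AC and HIST2H2BE were at 2.07 and 2.26 times. The 2 lower members, named after their values were seen, were HIST1H4C at 0.525 times (0.246 to 1.07) and HIST2H2AC at 0.485 times. Histone genes lie in near-identical copies, so reads could be split between members. Summed over 89 histone cluster rows, the smallest counts that fit, relative to the library totals, were 2.31 times the control value (2.20 to 2.42), and 1.67 times (1.58 to 1.77) without HIST1H2BK. With each row's counts raised to the multiple nearest its annotated transcript length, these ratios were 1.92 and 1.48. With the multiples that gave the lowest ratio, they were 1.29 (1.26 to 1.33) and 1.01 (0.970 to 1.04).

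The 13 mitochondrially encoded protein genes, subunits of the respiratory chain and ATP synthase, had a median of 0.44, again above all random lists. At least 1.5-fold higher were 4 of them: CYTB at 1.60 times (1.59 to 1.62), ND2 at 1.54 times, ND5 at 1.53 times and ND4 at 1.52 times. ND6, encoded on the other strand and named after its value was seen, was at 0.841 times (0.823 to 0.859). The share of mapped reads on chromosome M differed in the same direction. Under quantile normalization, which fixes the values of the highest ranks, the list's median was 0.07 and no longer stood apart.

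**Figure D2:**
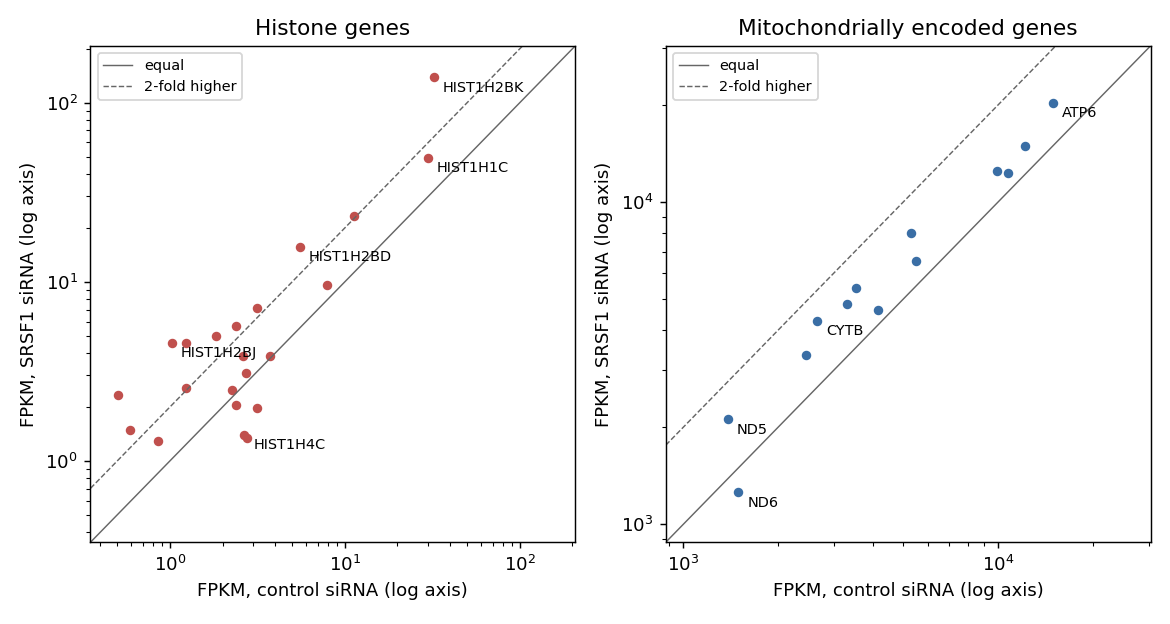
FPKM in the control siRNA library on the x axis and in the SRSF1 siRNA library on the y axis, both log axes, for the 22 measured histone genes and the 13 mitochondrially encoded genes. The solid line marks equal values and the dashed line 2-fold higher ones. HIST1H2BK went from 32.2 to 138 FPKM.

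Nuclear genes of the respiratory chain and ATP synthase lay on the other side, with a median of -0.16 over 46 members (percentile 0.63), and none reached 1.5-fold. NDUFB8 was at 0.714 times (0.633 to 0.805), UQCRC2 at 0.733 times, COX7C at 0.739 times and NDUFB10 at 0.739 times. These genes have short transcripts, with a median of 1202 bases against 3450 over protein-coding genes, and the difference between the libraries depended on length. The median difference was -0.16 in the 1002 protein-coding genes with the shortest transcripts and 0.03 in the 1001 with the longest (Spearman's rho 0.23 across 10013 genes, which are not independent replicates). With GC content rho was -0.13. After removal of this trend the list's median was -0.10 and no longer stood apart (percentile 7.96).

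**Figure D3:**
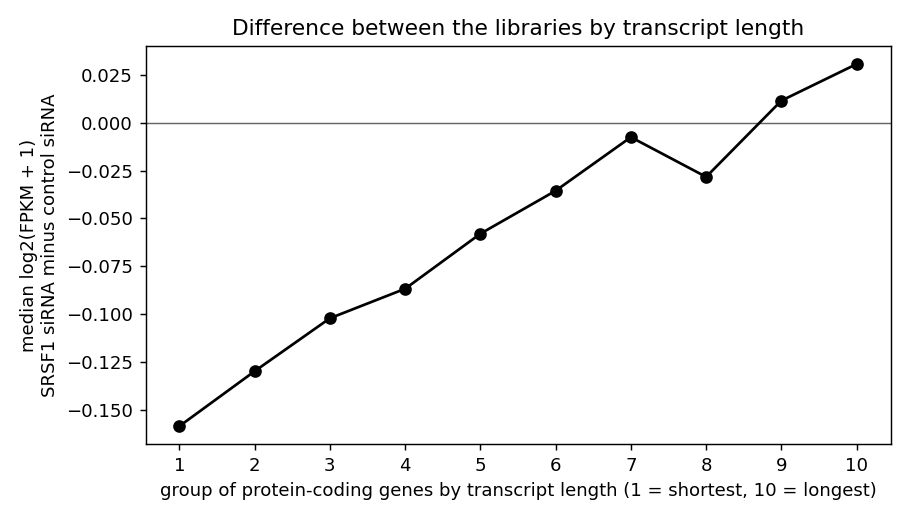
Median log2(FPKM + 1) difference, SRSF1 siRNA minus control siRNA, on the y axis for 10 groups of protein-coding genes, 10013 in all, ordered by transcript length on the x axis from shortest to longest. The median goes from -0.16 in the shortest group to 0.03 in the longest.

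The hnRNP genes, which encode RNA-binding proteins that often act against SR proteins in splicing, had a median of -0.18 over 23 members (percentile 1.37). Only HNRNPH3 was at least 1.5-fold lower, from 124 to 74.4 FPKM (0.602-fold, 0.579 to 0.625). HNRNPH1 was at 0.727 times, HNRNPLL at 0.727 times and HNRNPA1 at 0.774 times. HNRNPA1 has many processed pseudogenes that could share its reads. Against random lists not matched on expression the percentile was 3.39, inside the limits.

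Of the 33 lists tested, 5 stood above and 2 below random lists, where 1.65 would pass by chance if genes varied independently. Members of a list can vary together between any 2 libraries, so more could pass without an effect of SRSF1. Another 6 lists stood apart only under 1 or 2 of the alternatives. The G1/S genes driven by E2F had a median of 0.07 (percentile 99.1), with no member at least 1.5-fold higher and 2 lower, POLA1 and RBL1, named after their values were seen (0.646 and 0.632 times). DTL was at 1.41 times (1.31 to 1.51), E2F1 at 1.28 times, RFC3 at 1.24 times and DSCC1 at 1.18 times. The mean of this list was -0.01 and did not stand apart. The anti-apoptotic genes had a median of 0.16 over 9 members (percentile 99.0), with BIRC3 at 2.40 times (2.09 to 2.75), BIRC2 at 1.33 times, CFLAR at 1.34 times and BCL2L1 at 1.21 times. Transcripts of this list are longer than most, with a median of 4066 bases, and after removal of the length and GC trend it no longer stood apart (median 0.06, percentile 93.0). With a mean FPKM of at least 5 the anti-apoptotic list did not stand apart either (median 0.09). The NF-κB list had a median of 0.20 over 7 members (percentile 98.8), and of 0.10 over 14 with no filter. It shares BIRC3, and LIF was at 1.31 times, NFKBIA at 1.27 times and ICAM1 at 1.16 times.

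**Figure D4:**
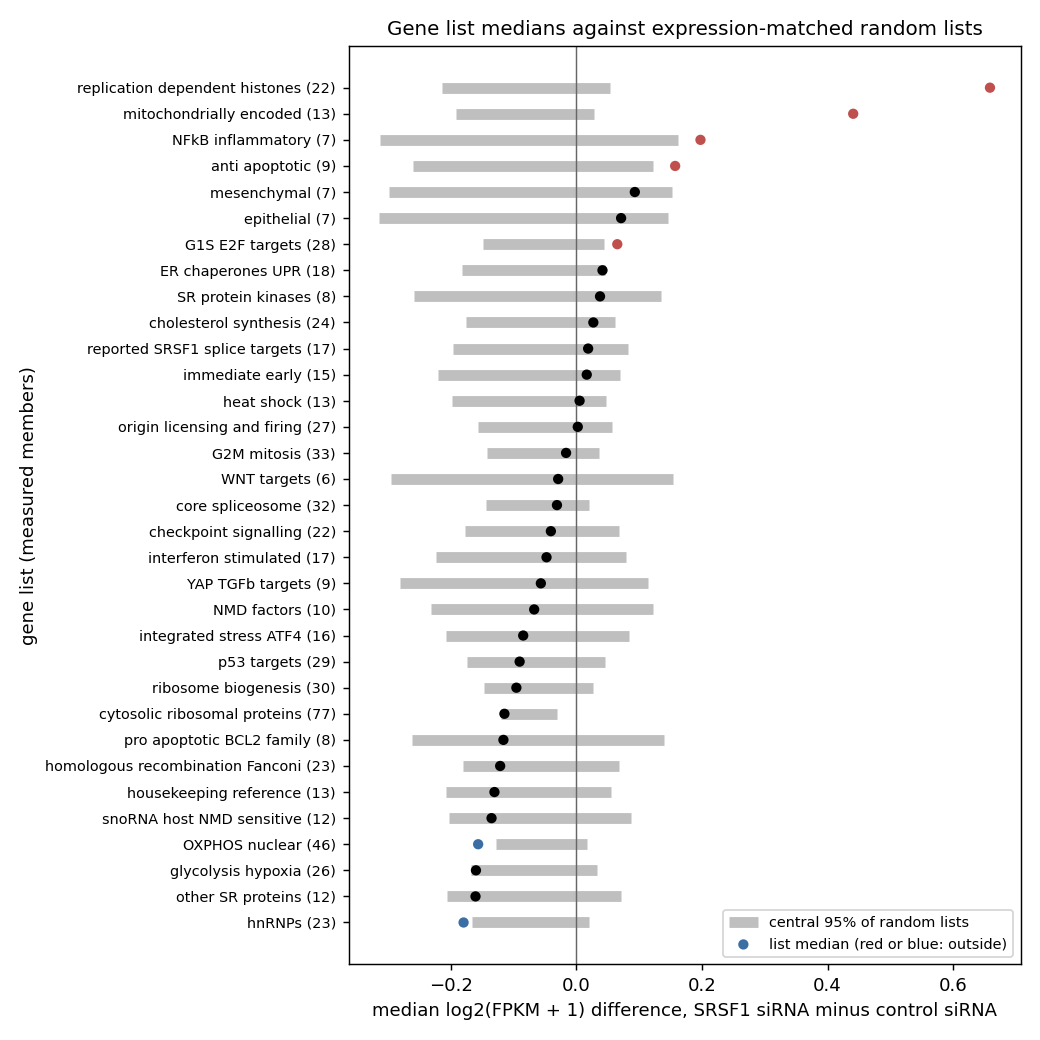
Points give the median log2(FPKM + 1) difference, SRSF1 siRNA minus control siRNA, of the 33 gene lists, and grey bars the central 95% of 10000 random lists matched on expression. Histone genes (0.66) and mitochondrially encoded genes (0.44) lie farthest to the right, and hnRNP genes (-0.18) farthest to the left.

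Lists of replication and repair genes did not stand apart, though single members were far below their control levels. Among homologous recombination and Fanconi anaemia genes (median -0.12 over 23 members), 2 were at least 1.5-fold lower: BRCA1 went from 17.3 to 9.33 FPKM (0.538-fold, 0.506 to 0.572) and FANCG from 11.4 to 6.34 FPKM (0.557-fold, 0.491 to 0.631). In the checkpoint list (median -0.04 over 22 members), RAD50, part of the complex that senses DNA breaks, went from 25.5 to 12.9 FPKM (0.508-fold, 0.481 to 0.536). ATRIP was at 0.647 times, and its interval (0.189 to 2.03) is wider than counting error because the recovered counts are the smallest that fit. Origin licensing and firing genes had a median of 0.00 over 27 members. CDC7, the kinase that fires replication origins, was at 0.560 times (0.518 to 0.606), and its activating subunits DBF4 and DBF4B were at 1.01 times (0.954 to 1.06) and 0.904 times (0.815 to 1.00). GINS1 was at 1.57 times (1.45 to 1.70). The values are sums over a gene and carry no information on the exons used in DBF4B, whose splicing the study's authors have linked to SRSF1. In the mitosis list (median -0.02 over 33 members) none reached 1.5-fold on the log2(FPKM + 1) scale, and HMMR and CENPA were at 0.650 and 0.681 times.

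Of 29 p53 target genes (median -0.09), 2 were at least 1.5-fold lower: DDB2, a damage sensor of nucleotide excision repair, at 0.537 times (0.462 to 0.623) and FDXR at 0.586 times (0.474 to 0.723). CDKN1A and MDM2, named after their values were seen, were at 1.11 times (1.02 to 1.21) and 1.09 times (1.05 to 1.13). Pro-apoptotic BCL2 family genes had a median of -0.12 over 8 members, with BAX at 0.823 times and PMAIP1 at 0.843 times. Heat shock genes had a median of 0.01, with HSPA1B, which has a near-identical copy, at 1.16 times and HSPE1 at 0.871 times. ER chaperone genes had a median of 0.04, with DNAJB9 at 1.34 times and CRELD2 at 0.742 times. ATF4 stress genes had a median of -0.08, with DDIT4, an inhibitor of mTORC1 signalling, at 0.485 times (0.331 to 0.701) and SHMT2 at 0.739 times. Interferon-stimulated genes had a median of -0.05, with IFI35 at 0.577 times and DDX60 at 0.503 times, but one of 0.15, above random lists (percentile 97.8), over the 7 members with a mean FPKM of at least 5. Immediate early genes had a median of 0.02, with KLF6 at 0.710 times and FOSB at 1.35 times.

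Core spliceosome genes had a median of -0.03 over 32 members, with SF3B3 at 0.637 times (0.616 to 0.659) and SF3B5 at 0.748 times. The other SR protein genes had a median of -0.16 over 12 members (percentile 8.37). After removal of the length and GC trend they stood below random lists (median -0.185, percentile 1.68). The SR protein kinases had a median of 0.04, with CLK2 at 0.791 times and DYRK1A at 1.18 times. Nonsense-mediated decay factors had a median of -0.07, with SMG9 at 0.678 times and UPF3B at 1.39 times. Of 12 snoRNA host genes, whose spliced RNAs are destroyed by that pathway (median -0.13), SNHG8 was at 0.548 times (0.471 to 0.637) and SNHG6 at 0.567 times (0.537 to 0.598). Genes reported elsewhere as splicing targets of SRSF1 had a median of 0.02 over 17 members. Of these, CCND1 fell and RPS6KB1, the kinase S6K1, was at 1.63 times (1.52 to 1.74). Ribosome assembly genes had a median of -0.10, with RRP1 at 0.592 times (0.549 to 0.638) and the methyltransferase FBL at 0.640 times (0.614 to 0.668). The 77 cytosolic ribosomal protein genes had a median of -0.11 (percentile 4.18), with RPL34 at 0.776 times.

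In metabolism, glycolysis and hypoxia genes had a median of -0.16 over 26 members (percentile 3.54), 3 of them at least 1.5-fold lower. These were ANKRD37 at 0.467 times (0.329 to 0.656), the histone demethylase KDM3A at 0.629 times (0.588 to 0.671) and PFKFB4, named after its value was seen, at 0.555 times. The glycolysis and hypoxia list stood below random lists with no filter and with the mean of the list. Cholesterol synthesis genes had a median of 0.03, with PMVK at 0.621 times and TM7SF2 at 0.644 times. This list stood above random lists with a mean FPKM of at least 5 (0.08, percentile 98.6) and after removal of the length and GC trend (0.06, percentile 98.1). WNT target genes had a median of -0.03 over 6 members. Among them CCND1 fell, and LEF1 was at 1.40 times. YAP and TGF-β target genes had a median of -0.06, with SKIL at 0.561 times and CTGF at 1.76 times. Epithelial genes had a median of 0.07 over 7 members, with OCLN at 1.26 times and KRT8 at 1.22 times. Mesenchymal genes had one of 0.09 over 7 members, with CALD1 at 1.83 times (1.47 to 2.28) and VIM at 0.678 times.

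Markers of fibroblasts, endothelium and red cells had no member with a mean FPKM of 1 or more in these libraries. Of 14 leukocyte markers, LCP1 (74.3 and 109 FPKM) and CD68 (218 and 198 FPKM) were expressed. Of 16 genes of intestinal differentiation, 2 were measured, CA2 at 0.873 times and the transcription factor CDX2 at 0.872 times. Reference genes did not move together: ACTB was at 1.43 times (1.41 to 1.46), HPRT1 at 1.46 times (1.39 to 1.54), GAPDH at 0.914 times (0.900 to 0.928) and TBP at 1.02 times (0.903 to 1.16), and the median of 13 reference genes was -0.13.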

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

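The tests with whole counts, protein-coding rows, totals without mitochondrial rows and trend removal were chosen after seeing the data. No gene of the naming rule that differed by 1.5-fold or more changed sign, and 846 of 918 values of named genes moved by less than their counting error, leaving out the filters and row types, which cannot change a single gene's value. The log2 difference of SRSF1, -1.63, became -1.58 with the median ratio set to 0 and -1.57 under quantile normalization. The counts past the 2-fold rule, 32 higher and 49 lower, moved under several alternatives. They were 67 and 165 with a pseudocount of 0.1, 49 and 100 with 0.5, 8 and 18 with a mean FPKM of at least 5, 85 and 141 with columns rescaled to a fixed sum, and 10 and 13 for protein-coding rows. With no filter 52 were higher, and from whole counts without a pseudocount 154 were lower. The 1.5-fold rule gave 138 and 485 and the 3-fold rule 6 and 7, by construction. The median of all genes, -0.0578, was -0.0661 with a pseudocount of 0.1, -0.0242 with no filter, -0.0507 with a mean FPKM of at least 5, -0.0113 with the median ratio set to 0, -0.0728 with columns rescaled to a fixed sum, 0.0134 under quantile normalization, -0.0681 from whole counts and -0.0318 without mitochondrial rows in the totals. Of the lists that stood apart, calls ended for G1/S genes with the mean of the list (-0.0120), hnRNP genes with unmatched random lists (-0.179), anti-apoptotic genes with a mean FPKM of at least 5 (0.0881) and after trend removal (0.0632), nuclear respiratory chain genes after trend removal (-0.0962), and mitochondrially encoded genes under quantile normalization (0.0662). Calls were gained by 6 lists: after trend removal by other SR protein genes (-0.185), immediate early genes (0.0759) and cholesterol synthesis genes (0.0571), with a mean FPKM of at least 5 by cholesterol synthesis genes (0.0833) and interferon-stimulated genes (0.155, from -0.0474), with columns rescaled by immediate early genes (0.0746), with no filter by glycolysis and hypoxia genes (-0.160) and epithelial genes (0.0562), and with the mean of the list by glycolysis and hypoxia genes (-0.206). Beyond what the construction of each alternative shows, the cause was not tested. Histone genes and NF-κB genes kept their calls wherever a value could be had, but with no filter their medians were 0.201, from 0.659, and 0.105, from 0.198. Other medians of lists that kept their call moved by more than 1.5 times as well: G1/S genes, 0.0653, to 0.118 with the median ratio set to 0 and 0.115 under quantile normalization, hnRNP genes, -0.179, to -0.104 under quantile normalization, and nuclear respiratory chain genes, -0.156, to -0.103 and -0.0895 under these 2. With a mean FPKM of at least 5, 3 lists, NF-κB among them, had under 5 members, and since no symbol was repeated, keeping the highest of repeated rows gave no value. No paired analysis was possible because there was 1 library per group. Depth limits genes with few fragments, and 1 library per group limits all results.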

Other observations

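Grouping expressed protein-coding genes by the letters that open their symbols, a grouping chosen after seeing the data, gave 111 families of at least 10 members. Of these, 6 stood above and 12 below matched random lists, where 5.55 would pass by chance if genes varied independently, which members of a family may not. After removal of the length and GC trend, the same 6 and 3 more (CDC, KIF and GPR) stood above, but only 8 of the 12 below, without the IFT, TRAPPC, DNAJC and NDUFB genes. Genes of the mitochondrial ribosome were lower as a group. The 47 MRPL genes of its large subunit had a median log2(FPKM + 1) difference of -0.22, with 38 below 0, and the 29 MRPS genes of its small subunit had one of -0.29, with 26 below 0. After removal of the length and GC trend the medians were -0.17 and -0.22, still outside the random lists, and under quantile normalization they were -0.16 and -0.23. The 15 PEX genes of peroxisome assembly had a median of -0.29, with 13 below 0. Families whose symbols name no shared process stood below random lists too, before and after trend removal. Among them were the 70 CCDC, 53 WDR and 10 SMIM genes, with medians of -0.16, -0.16 and -0.31. A place below random lists thus does not by itself point to a shared process. Of the families above random lists, the 37 UBE genes, mostly of ubiquitin transfer, had a median of 0.10 with 28 above 0, and the 10 AKAP genes, anchors of protein kinase A, one of 0.24.

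CCND1 and MYEOV are neighbours, which was looked up after both were seen to fall. In GENCODE 29 on GRCh38, CCND1 lies on chromosome 11 from 69641087 to 69654474 and MYEOV from 69294138 to 69367726, a gap of 273361 bases. The other 9 expressed protein-coding genes within 1 Mb of CCND1, 1 of them (ORAOV1) listed under an older symbol, had log2 differences between -0.37 (FADD) and 0.33 (CTTN), with a median of 0.04.

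The tests of length and GC content and of the sum over near-identical copies for the higher histone and mitochondrial genes were fixed before their results were seen. The use of whole multiples of the counts in that sum and the remaining tests below were chosen after. For histone genes, the median was 0.74 once the length and GC trend was removed (bootstrap 95% interval over members, taken as independent, 0.24 to 1.06). Short transcripts were lower in the SRSF1 siRNA library (median -0.16 in the shortest group), and histone transcripts are short (median 650.5 bases). The length trend thus ran opposite to the rise, so removing it tends to raise the median and says little about the cause. Reads moved between near-identical copies would leave the sum of the family's true counts level. The smallest counts that fit summed to 2.31 times the control value over the 89 rows. Whole multiples of them, up to the longest recovered gene model of the family, could lower this ratio to no less than 1.29 (1.26 to 1.33). If no true gene model was longer, reads moved among these rows were not the whole cause. Reads shared with copies outside these rows are not covered, as the counting tool is not known. Without HIST1H2BK the lowest ratio was 1.01 (0.970 to 1.04), so for the other copies moved reads stay open as an explanation. Whether poly(A) RNA was selected is not known, nor whether the histone reads came from RNA with a tail. More RNA without a poly(A) tail in the SRSF1 siRNA library would have raised 5 untailed RNAs outside the list. Their summed counts were 0.918 times the control value (0.805 to 1.05), or 0.886 times (0.795 to 0.987) with multiples nearest the annotated lengths. These values bear only on histone reads from untailed RNA. A larger share of cells in S phase stays open as an explanation. After trend removal the G1/S list lay at percentile 98.1, above random lists as this explanation needs. Its members went both ways, with an interval of its median from -0.06 to 0.12. The mean of the G1/S list, without trend removal, was -0.01 and inside the limits (percentile 83.2). Origin licensing and firing genes lay inside the limits after trend removal (median -0.03, percentile 61.5). These lists do not decide the question. Whether the histone difference comes from loss of SRSF1, and may then be a biological effect, was not tested beyond these 2 libraries.

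For the mitochondrially encoded genes, removal of the length and GC trend left a median of 0.52 (bootstrap 95% interval over members, taken as independent, 0.34 to 0.66). These genes share 1 chromosome and need not vary independently, so the interval may be too narrow. Their transcripts are short too (median 784 bases), so the length trend again ran opposite to the rise, and its removal says little about the cause. More mitochondria per cell might raise nuclear genes of the respiratory chain as well, but their median was -0.096 after trend removal (-0.20 to -0.03). These transcripts need not follow the number of mitochondria, which was not measured, so more mitochondria per cell are not excluded. A difference in RNA preparation between the 2 libraries, which are confounded with the groups, and a biological difference between the cells may each account for the higher values. Neither was tested.

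Both lists that lay below random lists were set against the length and GC trend. The hnRNP list kept a percentile of 0.955 after its removal. Its median transcript, 3691 bases, is close to the 3450 bases over protein-coding genes. Removal of the length trend could thus change this list little, so the result is only weak evidence against the trend. For nuclear respiratory chain genes the percentile rose to 7.96, inside the limits, as the median moved from -0.156 (-0.232 to -0.110) to -0.096 (-0.201 to -0.033). Whether short transcripts or a biological change caused the lower values of that list cannot be told apart, because the list's median transcript, 1202 bases, is short.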
